A study of Mus musculus with 4 samples.

How the data were processed

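Total RNA from whole thymus of 2 transgenic and 2 knockin samples was hybridised to Illumina MouseWG-6 v2.0 bead arrays, 1 sample per array. Per the labels' protocols, RNA was extracted with a Qiagen miRNeasy kit with DNase treatment, checked on a Bioanalyzer, and amplified to biotin-labelled cRNA with an Ambion kit. The series title speaks of thymocytes, whereas the tissue labels and the design text name whole thymus, which is the term used here. Groups and replicate numbers come from the sample titles, and each array was matched to its sample by the array name in the sample description.

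Per the file headers, the deposited scanner table was written by GenomeStudio 1.9.0 with no normalization and no error model. It holds the average bead signal intensity of 45281 probes per array, with lowest values near the background and no subtraction stated. It carries no detection p-value and no control probes. The authors' deposited value table gives processed intensity on a linear scale, with medians of 1.753, 1.772, 1.778 and 1.809, a floor of 0.002 on 23.7% to 24.0% of probes, and nearly equal distributions across arrays. GenomeStudio is named for it in the submitters' processing notes, while its background and normalization method are not given in the sources used here. Its probe identifiers are not paired with genes in the files used here, so only counts of probes were taken from it, on log2(value + 8).

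The design fixed before the data were examined called for neqc, which needs detection p-values or control probes, with normexp and no filter named as the substitute where these are missing. The substitute was used: normexp background correction with an offset of 50, log2, quantile normalization across the 4 arrays and all probes tested. Fitting used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 2 transgenic against 2 knockin arrays, two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The offset and the quantile step compress differences of dim probes and force equal distributions, so folds of dim genes are understated and a broad shift of the transcriptome would be removed. On simulated data with 200 changed probes among 45281, the same code recovered 38.8% of probes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 4 false calls. A simulated list shifted by log2 0.5 was called, as was 1 list without a shift among the remaining 23. Changed probes and list genes were drawn only from probes with a mean log2 above 8, and the simulated noise was independent between probes. Recovery of dimmer probes, or under variation that probes share, was therefore not measured.

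A background band was set for each array after seeing the data, as the most common signal plus 3 SDs of the values below it, giving limits of 151.4, 146.7, 149.1 and 152.1. A probe under its limit on every array of a group has only a bound there, and its fold is given as at least the bright group's mean over the dim group's mean, each dim array being taken at the higher of its limit and the probe's own signal, from normalised log2 values. Probe names in the scanner table are those of the array design. They were matched to current symbols through a RefSeq gene table of assembly GRCm38.p6, used for names and for gene order only. Of the probes 34781 (76.8%) matched a single gene, 22864 by symbol and 11917 by synonym, 282 matched several and 10218 none, leaving 19579 genes. For the 9010 genes with several probes the probe with the highest mean over all arrays stood for the gene, and disagreeing probes are named.

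Gene lists (26, covering thymocyte stages, thymic stroma, other cell types the organ can hold, cell programmes, miR-181 targets, neighbours of the Mir181c and Mir181d locus and sex-linked transcripts) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Some genes stand in more than 1 list, such as Cd69. Named genes follow a rule fixed at the same time: up to 15 genes per direction with the largest change among those past the threshold with separated groups, filled by the smallest p, plus the 4 members of each list with the smallest p, the sex-linked transcripts and any probe of the Mir181 genes, of which none was found by name. Of the list members the rule names, the text prints examples, and some results are not reported here. Lrrc8b, Csf3r, the granulocyte genes Lcn2, Retnlg and Ltf, the dimmer probes of H4c12, Sytl3 and Pisd-ps3 and the eosinophil genes of the closing part were named after their values were seen.

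Alternatives were no background correction, an offset of 16, median scaling, cyclic loess, the replicate number as a block, an intensity trend with robust priors, leaving out each array, other thresholds, 1 probe per gene, the mean of all probes of a gene, other list tests and the authors' value table. Filters on dim probes and a block by place on the slide were added after seeing the data. When an array is left out, the lone remaining sample of its group is assumed to vary like the other group. All arrays shared 1 slide, with the transgenic samples at places A and B and the knockin samples at E and F by the array names. Genotype therefore cannot be told apart from the end of the slide. The block by place compares outer with inner places only and does not adjust for this. A search for miR-181 seed sites was not run, as transcript sequences were not used here.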

Results

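Gene expression was measured in whole thymus of C57BL/6 mice of 2 genotypes, a line carrying a miR-181d transgene and a line carrying a miR-181d knockin allele. miR-181d belongs to the miR-181 family of microRNAs, which are abundant in immature thymocytes and are known for tuning T cell receptor signalling. Each genotype had 2 arrays, and each array read 45281 probes with total RNA from the organ. The labels do not state how either allele was built or which way miR-181d changes in the knockin, and wild-type thymus was not analysed here, so a value below only places one genotype against the other. Median signal was 145.8 and 140.5 on the transgenic arrays and 141.7 and 145.7 on the knockin arrays, and 42.6% to 44.5% of probes lay above the background band of their array. Across the 9187 brightest probes, which are not independent replicates, the arrays correlated pairwise at r = 0.973 to 0.985. Within a genotype r was 0.9826 (transgenic) and 0.9829 (knockin). Between genotypes it was 0.9854, 0.9837, 0.9823 and 0.973, so the arrays did not group by genotype. The small number of arrays limits the precision of each value. The sex-linked transcripts below show that the 2 knockin arrays read tissue of different animals. For the 2 transgenic arrays the labels do not state separate mice, so the spread between them may be technical.

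The comparison of the series asks which transcripts differ between thymus of the transgenic line and thymus of the knockin line. Among those that did were 5 neighbouring genes around Gbp11 and the Lrrc8 family, 3 core histone genes higher in the transgenic line, and 6 genes of granulocyte and other myeloid products lower in it, and 9 further called genes were of varied function. With limma and a Benjamini-Hochberg adjusted p under 0.05, 36 probes passed, 23 higher and 13 lower in transgenic thymus. Taking the brightest probe of each gene, 23 named genes passed, 12 higher and 11 lower. Of the 36 probes, 6 matched no single gene. Sytl3, Pisd-ps3 and H4c12 passed only on a dimmer probe. For Sytl3 and Pisd-ps3 that probe was higher in transgenic thymus by log2 0.88 and 1.09 (limma adjusted p = 0.0381 and 0.0421). In all 36 probes both transgenic arrays lay on the same side of both knockin arrays, which the call itself nearly requires. At an unadjusted p under 0.05 there were 2097 probes against 2264 that chance alone would give. The count depended on the processing: with median scaling in place of quantile normalization 2 probes passed, both higher in transgenic thymus, and without background correction 3 passed, all higher. It was 70 with an offset of 16 in the background correction, 112 with an intensity trend and robust priors, and 364 (193 higher, 171 lower) with the place on the slide as a block, which was added after seeing the data. Changes below are log2 intensity, transgenic minus knockin, with the limma standard error and adjusted p, and n = 2 arrays per group.

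The largest difference was in Gbp11, a member of the guanylate-binding protein family of interferon-inducible GTPases. Its probe was bright in both transgenic arrays (10.98 ± 0.06, SD, n = 2) and not above background in either knockin array, giving at least 23.8-fold higher intensity in transgenic thymus (log2 4.88, SE 0.102, adjusted p = 4.66e-08). Lrrc8d, a subunit of the volume-regulated anion channel, was 6.36-fold higher (log2 2.67, SE 0.116, adjusted p = 2.46e-05). Zfp326, a zinc finger protein of the RNA splicing machinery, was 3.01-fold higher (log2 1.59, SE 0.105, adjusted p = 8.28e-04), and all 3 of its probes passed. The transcript D830014E11Rik was higher by log2 1.82 (SE 0.138, adjusted p = 0.0021), with 1 of the 2 knockin arrays above background. Lrrc8c, another subunit of the same channel, went the opposite way and was 2.11-fold lower in transgenic thymus (log2 -1.08, SE 0.10, adjusted p = 0.00544). These 5 genes stand close together in the gene order of the mouse reference annotation. Of the 6 measured genes from Gbp11 to Zfp326, the remaining member, Lrrc8b, was not above background on any array. The 8 measured genes within 20 places on either side differed by at most 0.18 in size, and 3 of them were above background. Gbp11 and Lrrc8d passed under every alternative that gave them a value. Zfp326 missed the threshold with median scaling (adjusted p = 0.101, alternatives 2.33e-10 to 0.101), and D830014E11Rik and Lrrc8c missed it with median scaling and without background correction (highest adjusted p 0.201 and 0.155).

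**Figure D1:**
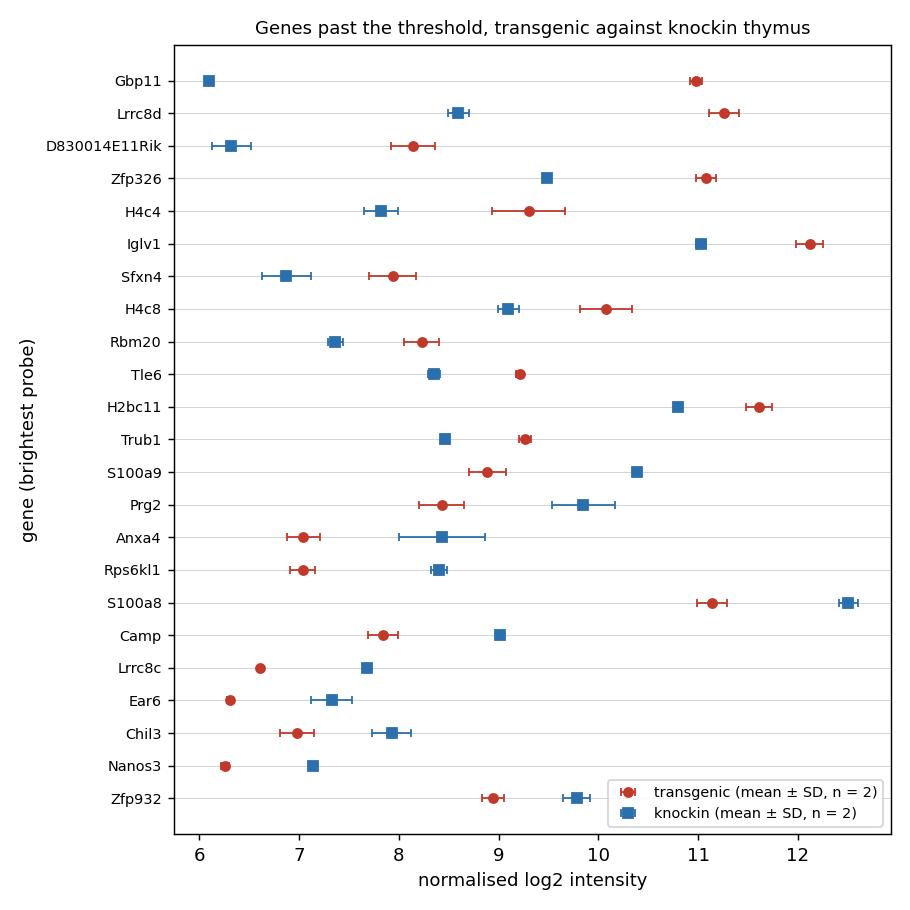
Normalised log2 intensity (horizontal axis) of the 23 named genes past the threshold (vertical axis), with circles for transgenic and squares for knockin thymus, each the mean of 2 arrays with its SD. Gbp11 has the widest separation, 10.98 against 6.10, and the myeloid genes S100a9, Prg2, S100a8 and Camp lie to the left in transgenic thymus.

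**Figure D2:**
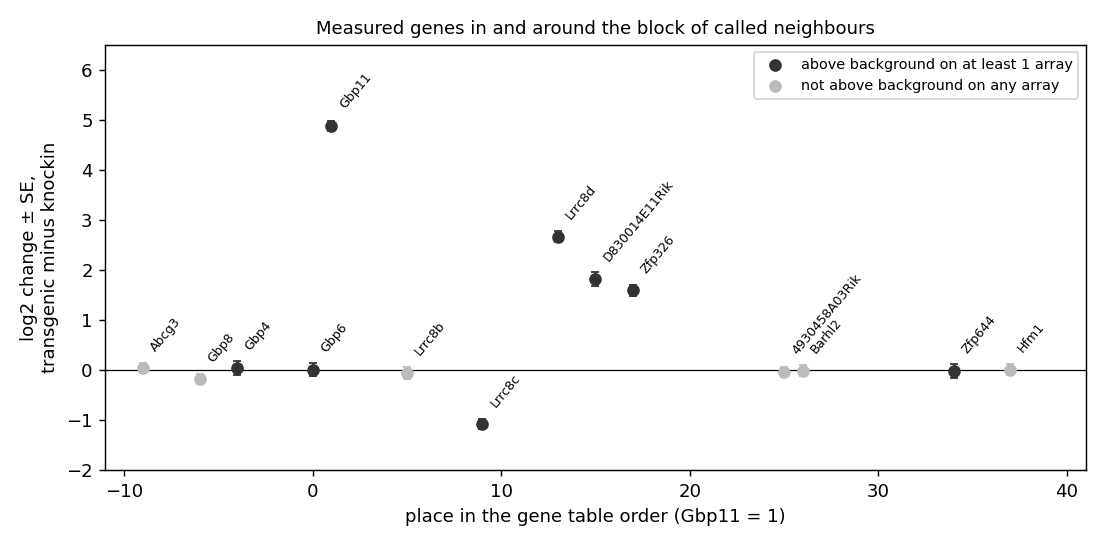
Log2 change with its standard error (vertical axis, transgenic minus knockin, n = 2 per group) of measured genes by their place in the gene order, counted from Gbp11 as 1 (horizontal axis), with grey points for genes not above background on any array. Gbp11, Lrrc8d, D830014E11Rik and Zfp326 lie above 0 and Lrrc8c below, while flanking genes stay within 0.18 of 0.

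Core histone genes of the histone clusters were among the other transcripts higher in the transgenic line. H4c4 was 2.79-fold higher (log2 1.48, SE 0.164, adjusted p = 0.0160), H4c8 was 1.97-fold higher (log2 0.98, SE 0.135, adjusted p = 0.0450) and H2bc11 was 1.75-fold higher (log2 0.81, SE 0.108, adjusted p = 0.0418). A probe of H4c12 also passed (log2 1.22, adjusted p = 0.0217), whereas the brighter H4c12 probe did not (adjusted p = 0.0703). H4c1 and H2bc13 had values of 0.89 and 0.96 with adjusted p of 0.0516 and 0.0619. Histone genes of these clusters are near-identical copies, so a probe may read several of them and the single names are uncertain. The second H4c8 probe was not above background on any array.

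Other genes higher in transgenic thymus were of varied function. Iglv1, a variable segment of the immunoglobulin lambda light chain, was 2.12-fold higher on its brighter probe (log2 1.09, SE 0.110, adjusted p = 0.00807), its second probe passed too, and related lambda segments may share the signal. Tle6, of the Groucho-related family, was 1.81-fold higher (adjusted p = 0.0217), the pseudouridine synthase Trub1 was 1.75-fold higher (adjusted p = 0.0310) and Rbm20, a splicing regulator, was 1.82-fold higher (adjusted p = 0.0421). Sfxn4, a mitochondrial sideroflexin, had a log2 change of 1.07 (adjusted p = 0.0468) on its brighter probe and -0.06 on the other, which was above background on all 4 arrays. For Trub1, 2 of 5 probes passed and 1 was not above background on any array. Without transgenic replicate 2, Sfxn4, H4c8, Rbm20, Tle6, H2bc11 and Trub1 all missed the threshold, with the same direction and log2 values of 0.90, 0.80, 0.74, 0.83, 0.72 and 0.76. Rbm20 also missed it without knockin replicate 1 (log2 0.81) and H2bc11 without knockin replicate 2 (log2 0.79).

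Products of neutrophils, eosinophils and other myeloid cells made up 6 of the 11 genes lower in transgenic thymus. S100a9 and S100a8, the calprotectin subunits abundant in neutrophils, were 2.83-fold and 2.58-fold lower (log2 -1.50, SE 0.117, adjusted p = 0.00218, and log2 -1.37, SE 0.115, adjusted p = 0.00314). Camp, the cathelicidin of neutrophil granules, was 2.24-fold lower (log2 -1.17, SE 0.111, adjusted p = 0.00544). Prg2, the eosinophil major basic protein, was 2.67-fold lower (log2 -1.42, SE 0.160, adjusted p = 0.0163). Ear6, an eosinophil-associated ribonuclease, was not above background in transgenic thymus and at least 1.91-fold lower (adjusted p = 0.0213). Its near-identical relatives can share signal, and Ear1 had a value of -0.77 (adjusted p = 0.0703). Chil3, a chitinase-like protein of myeloid cells, was 1.93-fold lower on its brightest probe (adjusted p = 0.0455) and at -0.81 and -0.31 on the others, which did not pass, and Fpr2, a formyl peptide receptor of phagocytes, had a value of -0.88 (adjusted p = 0.0647). Among haemoglobin transcripts, Hba-a1 was at -0.75 (adjusted p = 0.726) and Hbb-b1 at -0.44 (adjusted p = 0.858). Over the alternatives, log2 values ranged from -1.63 to -1.37 for S100a9 and from -1.47 to -1.26 for S100a8. They ranged from -1.30 to -0.98 for Camp and from -1.64 to -1.19 for Prg2. Ear6 missed the threshold without transgenic replicate 2 (log2 -0.997), and Chil3 without that array (log2 -0.83) or without knockin replicate 2 (log2 -0.81).

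The remaining genes lower in transgenic thymus included a neighbour of the microRNA itself. Nanos3, an RNA-binding protein known from germ cells, stands 1 place from Mir181d in the gene order. It was above background in both knockin arrays, in neither transgenic array, and at least 1.68-fold lower in transgenic thymus (log2 -0.89, SE 0.101, adjusted p = 0.0163). Rps6kl1, a ribosomal S6 kinase-like protein, was 2.58-fold lower (log2 -1.37, SE 0.111, adjusted p = 0.00257). Anxa4, a calcium-dependent phospholipid-binding protein, had a log2 change of -1.39 (adjusted p = 0.0354) on its brightest probe and -0.01 on another, the third not being above background. Zfp932, a zinc finger protein, was 1.79-fold lower (log2 -0.84, adjusted p = 0.0450) on the brightest of 3 probes and had a value of -0.50 (adjusted p = 0.449) on another, the third not being above background. Gpr83, a receptor known from regulatory T cells, and the lipase-family gene Pnpla3 had values of -0.99 and -0.90 with adjusted p of 0.0703 and 0.0590. Anxa4 missed the threshold without transgenic replicate 1 (log2 -1.28), and Zfp932 without transgenic replicate 1, transgenic replicate 2 or knockin replicate 1 (log2 -0.76, -0.92 and -0.74). With median scaling or without background correction, each called gene of this and the preceding 3 paragraphs missed the threshold while keeping its direction. With the mean of all probes of a gene, Sfxn4, H4c8, Trub1, Chil3, Anxa4 and Zfp932 missed it at 0.50, 0.54, 0.50, -0.69, -0.44 and -0.44 (adjusted p = 0.579, 0.219, 0.276, 0.276, 0.644 and 0.452). H4c4, Rbm20, H2bc11, Prg2 and Ear6, which have 1 probe each, missed it there with unchanged values (adjusted p = 0.0689, 0.0945, 0.0689, 0.0689 and 0.0548).

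Sex-linked transcripts separated 1 array from the rest. Signal of Xist, the transcript of the inactive X chromosome, was 4366 and 4392 on the transgenic arrays, 4570 on knockin replicate 1 and 129.5 on knockin replicate 2. The Y-linked genes went the other way, with Ddx3y at 3519 on knockin replicate 2 against 484.4, 494.3 and 553.7 elsewhere, and Eif2s3y at 909.8 against 125.0 to 133.4. Kdm5d read 282.6 on knockin replicate 2 and 127.2 to 131.9 on the others, and Uty read 169.6 against 148.0 to 150.3. Knockin replicate 2 thus carried a male pattern and the other 3 arrays a female one, and the list of sex-linked transcripts had a median of -0.78 (camera adjusted p = 0.0757, and 0.864 with an estimated correlation), passing with an offset of 16, with the replicate number or the place on the slide as a block and without knockin replicate 1 (adjusted p = 0.0267, 0.0184, 0.0441 and 2.74e-08). Without knockin replicate 2, 89 probes passed, 57 higher and 32 lower in transgenic thymus, and 32 of the 36 probes were among them. Without knockin replicate 1 the count was also 89, without transgenic replicate 1 it was 74, and without transgenic replicate 2 it was 24.

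Among 26 gene lists fixed before the data were examined, granulocyte genes had the median furthest from 0. Of 11 measured members 10 were lower in transgenic thymus, with a median of -1.10 (camera adjusted p = 1.01e-20). With an estimated correlation the list did not pass (adjusted p = 0.781, unadjusted p = 0.0415, and a range of 2.77e-33 to 0.781 over the alternatives). S100a9, S100a8 and Camp passed over all probes, and 7 members adjusted over the list alone, the others being Ngp at -1.22, Lcn2 at -1.10, Retnlg at -0.74 and Ltf at -1.15, all of them neutrophil granule or secretory products. Csf3r, the receptor of granulocyte colony-stimulating factor, had a value of 0.02.

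Immediate-early and heat-shock genes, which respond within minutes to stimulation or stress, were lower in transgenic thymus by a small amount. The list of 20 had a median of -0.15 with 19 members below 0 (camera adjusted p = 2.29e-05), and adjusted p = 0.781 with an estimated correlation, the highest over the alternatives. Without knockin replicate 2, the male sample, the median was -0.098 (adjusted p = 0.00577). No member passed over all probes by limma, 4 had an unadjusted p under 0.05, and Egr1 at -0.45 passed adjusted over the list alone. Its relatives Egr2 and Egr3, which like Egr1 are induced by T cell receptor signals, had values of -0.38 and -0.33.

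Stromal and antigen-presenting cell lists showed small shifts to lower values in transgenic thymus. Fibroblast and extracellular matrix genes had a median of -0.14 over 17 members (camera adjusted p = 8.81e-04), macrophage genes -0.078 over 18 (adjusted p = 0.00571) and dendritic cell and MHC class II genes -0.12 over 16 (adjusted p = 0.0320). With an estimated correlation the adjusted p was 0.864 for all 3 lists. Igfbp4, an insulin-like growth factor binding protein, had a value of -0.71 and passed adjusted over its list alone, and no member of the 3 lists passed over all probes, where 5 had an unadjusted p under 0.05. Apoe and Timd4, both expressed by macrophages, had values of -0.43 and -0.35. These shifts rested on single arrays. Without knockin replicate 2, the male sample, the fibroblast median was 0.018 (adjusted p = 0.896, alternatives 3.25e-11 to 0.896), the macrophage median -0.052 (adjusted p = 0.217, alternatives 1.22e-04 to 0.870) and the dendritic cell median -0.044 (adjusted p = 0.852, alternatives 1.42e-04 to 0.870). Without transgenic replicate 1 the macrophage and dendritic cell lists missed the threshold too (adjusted p = 0.165 and 0.0856), as did the dendritic cell list without transgenic replicate 2 (adjusted p = 0.0900). Medians were larger in size without knockin replicate 1, at -0.33 for fibroblast, -0.17 for macrophage and -0.23 for dendritic cell genes, and the macrophage median was -0.031 without transgenic replicate 1 and -0.16 without transgenic replicate 2.

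**Figure D3:**
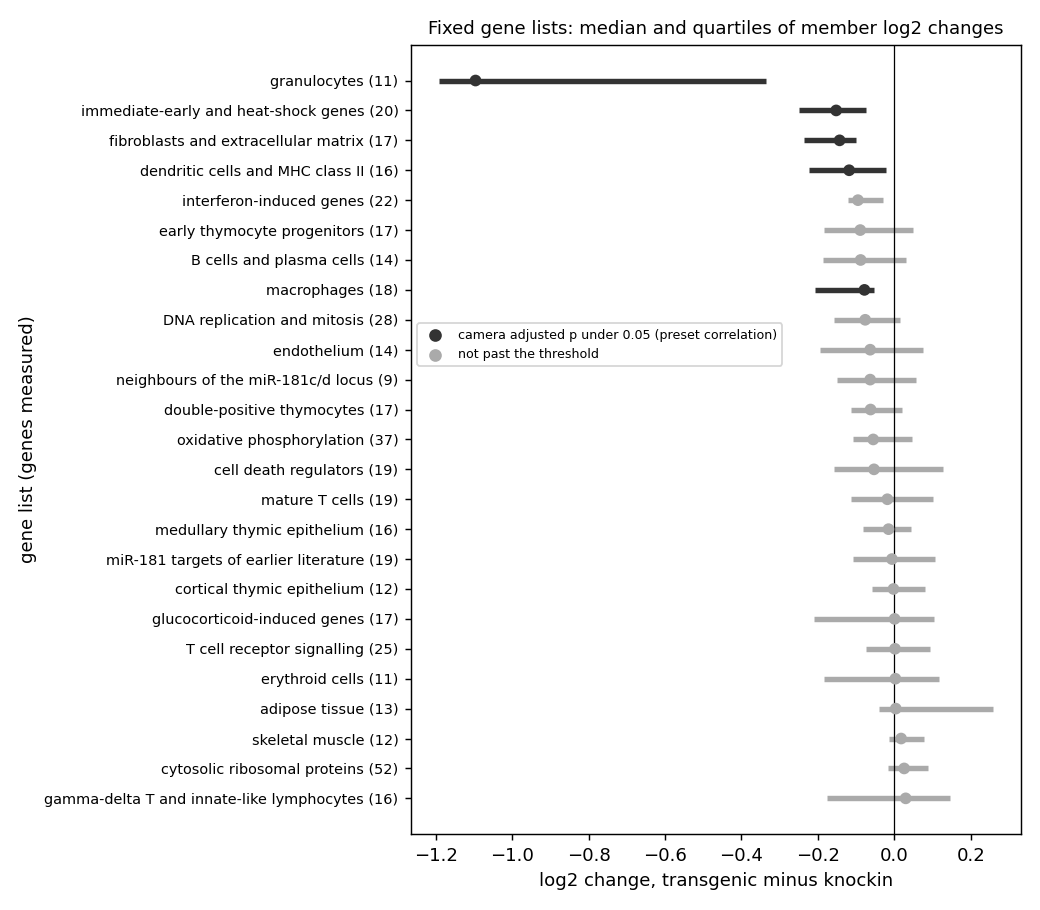
Median (point) and quartiles (line) of the log2 changes of member genes, transgenic minus knockin (horizontal axis), for 25 of the fixed lists with the number of genes measured (vertical axis), the sex-linked list being left out. Dark marks are the 5 lists past a camera adjusted p of 0.05 with the preset correlation, all below 0, and granulocytes stand apart at -1.10.

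Thymocyte lists did not pass. Genes of double-positive thymocytes, the most numerous cells of the thymus, had a median of -0.062 over 17 members (camera adjusted p = 0.187), and early progenitor genes -0.089 over 17 (adjusted p = 0.166). Mature T cell genes had a median of -0.018 over 19 members (adjusted p = 0.806), and genes of gamma-delta T and innate-like lymphocytes 0.030 over 16 (adjusted p = 0.850). No member of these 4 lists passed over all probes by limma, where 9 had an unadjusted p under 0.05. Adjusted over the list alone, the gut-homing integrin Itgb7 was higher at 0.51 and the activation marker Cd69 lower at -0.44, and among innate-like genes Klrd1 and Il18r1 were higher at 0.58 and 0.40. Bcl6 and Lmo2 had values of -0.32 and -0.42. Both lists of immature thymocytes leaned on single knockin arrays, since double-positive genes passed without knockin replicate 2 (median -0.18, adjusted p = 0.00181, alternatives up to 0.870) and early progenitor genes without knockin replicate 1 (median -0.15, adjusted p = 0.00240, alternatives up to 0.896). Components of T cell receptor signalling had a median of 0.002 over 25 members (adjusted p = 0.850), with Lcp2 at 0.34 and Cd2 at 0.23.

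Genes reported in earlier literature as miR-181 targets did not differ as a group. Their median was -0.006 over 19 members (camera adjusted p = 0.850), with 9 values above 0 and 10 below. Cd69 at -0.44 was the single member to pass adjusted over the list alone, and none passed over all probes by limma, where 3 had an unadjusted p under 0.05. The phosphatase Dusp6 and the survival factor Bcl2 had values of -0.33 and -0.36, and Bcl2l11, the pro-apoptotic Bim, had a value of 0.27. Neighbours of the Mir181c and Mir181d locus had a median of -0.063 over 9 members (adjusted p = 0.0757). Nanos3 was the only member past the threshold, the others differing by at most 0.181 in size, and the list passed fry's test for change in either direction (adjusted p = 0.0139). The list median turned to 0.067 without transgenic replicate 2 and was -0.009 without knockin replicate 2. This list also passed camera without transgenic replicate 1 (median -0.16, adjusted p = 0.0339) and without knockin replicate 1 (median -0.049, adjusted p = 0.0439), with alternatives up to 0.870.

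The other cell type lists did not pass in camera. Medians were -0.002 for cortical thymic epithelium over 12 members (adjusted p = 0.850), where median and test differed in sign, and -0.015 for medullary thymic epithelium over 16 (adjusted p = 0.933). Endothelial genes had a median of -0.063 over 14 members (adjusted p = 0.351), and Plvap at -0.57 passed adjusted over the list alone. B cell and plasma cell genes had a median of -0.088 over 14 (adjusted p = 0.0757), and passed with the mean of all probes of a gene (median -0.10, adjusted p = 0.0354) and over probes brighter than the median probe (median -0.13, adjusted p = 0.0428), with alternatives up to 0.864. Erythroid genes had a median of 0.003 over 11 (adjusted p = 0.806), with the test pointing lower and 6 members above background. Over probes brighter than the median probe, a filter added after seeing the data, this list passed lower in transgenic thymus (median -0.32, adjusted p = 0.0143, alternatives up to 0.980), and Hba-a1, Hbb-b1 and Car2 had values of -0.75, -0.44 and -0.32. The median was 0.018 for skeletal muscle genes over 12 members (adjusted p = 0.822). Adipose genes had a median of 0.004 over 13 (adjusted p = 0.180) that became 0.17 without transgenic replicate 2 and 0.23 without knockin replicate 2 (adjusted p = 0.0121 and 0.00355, alternatives up to 0.911).

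Cell programme lists outside the immediate-early genes did not pass either. DNA replication and mitosis genes had a median of -0.076 over 28 members (camera adjusted p = 0.0706), with Plk1 at -0.38 and Pcna at -0.27, and passed without knockin replicate 1 (median -0.19, adjusted p = 2.85e-05, alternatives up to 0.880) and with the place on the slide as a block (adjusted p = 0.0118). Interferon-induced genes had a median of -0.095 over 22 (adjusted p = 0.180). Their direction depended on the knockin array, with -0.35 without knockin replicate 1 (adjusted p = 3.79e-14) and 0.18 without knockin replicate 2 (adjusted p = 1.49e-04), and alternatives up to 0.965. Gbp2, an interferon-induced relative of Gbp11, had a value of 0.27. Glucocorticoid-induced genes had a median of 0.001 over 17 (adjusted p = 0.850), with the test pointing lower and passing without transgenic replicate 1 (median -0.059, adjusted p = 0.0339, alternatives up to 0.987). Cell death regulators had a median of -0.053 over 19 (adjusted p = 0.526), and adjusted over the list alone Bik was lower at -0.69 and the death receptor Tnfrsf10b higher at 0.38. The median of this list was -0.072 without knockin replicate 2 and 0.015 without knockin replicate 1. Cytosolic ribosomal protein genes had a median of 0.026 over 52 (adjusted p = 0.209), passing without transgenic replicate 1 (median 0.088, adjusted p = 0.0339, alternatives up to 0.970), and oxidative phosphorylation genes -0.055 over 37 (adjusted p = 0.361), passing with median scaling (median -0.11, adjusted p = 0.0329, alternatives up to 0.886). Median scaling also took double-positive thymocyte genes (median -0.12, adjusted p = 0.0401), replication and mitosis genes (median -0.11, adjusted p = 0.0214) and the neighbours of the Mir181c and Mir181d locus (median -0.083, adjusted p = 0.0487) past the threshold. When single arrays were left out, the oxidative phosphorylation median ranged from -0.061 without knockin replicate 2 to 0.025 without transgenic replicate 1. With an estimated correlation or with fry's directional test no list passed, where 1 and 2 lists had an unadjusted p under 0.05.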

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

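The filters on dim probes, the place on the slide and the probes of the authors' table with a mean above 20 were chosen after seeing the data. The 23 called genes kept their direction under every alternative that gave them a value. For the leave-outs this follows from the separated groups. Passing the threshold with an array left out is weak evidence of stability, as the spread then comes from the 1 pair of arrays left whole. Of the 23, 22 kept their call with cyclic loess, 20 with an offset of 16 and 15 with the replicate number as a block. The call held for 12 with the mean of all probes, 3 without background correction and 2 with median scaling. The 8 genes lost with the block were Sfxn4, Rbm20, Tle6, H2bc11, Trub1, Anxa4, Chil3 and Zfp932 (limma adjusted p = 0.0522 to 0.0913). Against 36 probes, limma called 3 without background correction, 70 with an offset of 16, 2 with median scaling, 112 with an intensity trend and robust priors, 23 with 1 probe per gene (fewer probes tested), and 24 to 89 when single arrays were left out. The authors' value table gave 0 calls by limma over all probes, with 3299 at an unadjusted p under 0.05, and 55 over probes with a mean above 20. The cause of these differences was not tested. The planned filters on detection p were not run, because the scanner table has none, and the alternative without a filter is the fit reported.

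Replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.225 over all probes and -0.401 over bright ones. With the replicate number as a block 38 probes passed, 24 of them among the 36. The crossed pairing, which is also the outer or inner place on the slide, gave 364 calls as a block.

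Against 5 gene lists, 9 passed with median scaling, 3 over probes with a mean log2 above 8, 5 to 10 when single arrays were left out, and 0 with an estimated correlation or with fry's directional test, where 1 and 2 lists had an unadjusted p under 0.05. Against 4 list members past the threshold, limma called 0 without background correction and 0 with median scaling (51 and 42 at an unadjusted p under 0.05), 8 with an offset of 16, 8 with trend and robust priors, 21 with the place on the slide as a block, and 4 to 16 when single arrays were left out.

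In 16 uncalled lists the direction of the test turned under some alternative. With an offset of 16 the medians were -0.015 for medullary epithelium and 0.001 for T cell receptor signalling, and with median scaling -0.025 for cortical epithelium and -0.041 for T cell receptor signalling. The mean of all probes gave 0.006 for T cell receptor signalling, and probes with a mean log2 above 8 gave 0.071 for mature T cells, 0.007 for medullary epithelium and -0.041 for adipose tissue. When single arrays were left out, medians ranged from -0.048 to 0.225 for adipose tissue, -0.052 to 0.042 for T cell receptor signalling, -0.048 to 0.069 for cortical thymic epithelium, -0.090 to 0.044 for medullary thymic epithelium, -0.142 to 0.015 for endothelium, -0.110 to 0.060 for glucocorticoid-induced genes, -0.031 to 0.060 for miR-181 targets, -0.008 to 0.088 for cytosolic ribosomal proteins, -0.175 to 0.007 for double-positive thymocytes, -0.005 to 0.022 for gamma-delta T and innate-like lymphocytes, -0.146 to 0.034 for early thymocyte progenitors, -0.063 to -0.018 for mature T cells, -0.012 to 0.037 for skeletal muscle, -0.084 to 0.097 for erythroid cells, -0.185 to 0.047 for DNA replication and mitosis, and -0.350 to 0.177 for interferon-induced genes. Uncalled genes that turned ranged from -0.286 to 0.018 for Myh4, -0.020 to 0.233 for Mb, -0.258 to 0.067 for Zswim4, -0.011 to 0.426 for Slamf1, -0.453 to 0.023 for Sparc, -0.80 to 0.19 for Oasl2, -0.054 to 6.14 for Xist, -3.50 to 0.13 for Eif2s3y and -1.60 to 0.041 for Kdm5d. The last 3 follow from the sex of knockin replicate 2. For the others the cause was not tested. As for signal over background, 42.6% to 44.5% of probes on each array lay above the background band.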

Other observations

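All tests in this part were chosen after the results were seen. For the granulocyte, histone and replication genes of this part, above background means above the limit on at least 2 of the 4 arrays. Eosinophil genes were looked at as a group only after Prg2 and Ear6 had passed, so the group is not independent evidence. Beside Prg2 and Ear6, values were -0.75 for Ear2, -0.81 for Ear10 and -0.77 for Ear1, none of these 3 past the threshold (adjusted p = 0.156, 0.229 and 0.0703), while Epx and Prg3 had -0.24 and -0.21 and the receptors Il5ra and Ccr3 0.12 and 0.04. A probe named EAR4 on the array, which matched no single gene, passed lower in transgenic thymus by limma (log2 -0.87, adjusted p = 0.0381). The ribonucleases of the Ear family are near-identical, so their probes are not independent.

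Clustered histone genes were taken as a set after the 3 calls were seen, and the 54 above background include those 3, so the values partly restate them. The set did not pass camera with an estimated correlation (p = 0.0814). By histone class, with classes not tested against each other, medians were 0.90 over 12 H4 genes, 0.81 over 13 H2B genes, 0.57 over 11 H3 genes and 0.52 over 3 H1 genes, and 0.022 over 15 H2A genes. At an unadjusted p under 0.05 there were 12 H4, 12 H2B, 11 H3 (1 of them lower) and 2 H1 genes and 0 H2A genes by limma. Most H2A probes lie near the top of the signal range, up to a mean log2 of 15.53, but the 5 with a mean under 12 had a median of 0.15 and a highest value of 0.41. The mean over the 54 genes was 10.67 and 11.00 on the transgenic arrays and 10.28 and 10.33 on the knockin arrays. The 9 measured histone genes outside the clusters had a median of -0.06, with values from -0.25 for H1f10 to 0.39 for H1f0.

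For the granulocyte genes, the sex of knockin replicate 2 was tested first. With the 3 female arrays the median of the 10 genes above background was -0.757, against -1.12 with all arrays, and 9 of 10 lay below 0. Without knockin replicate 1 the median was -1.295. Sex is therefore not the whole cause, and whether it is any part cannot be told from 1 female knockin array. More blood in the knockin samples may account for part of the granulocyte pattern and cannot be told apart from a change in resident granulocytes. The 11 haemoglobin probes had a median of -0.47. The erythroid list, which holds haemoglobin genes too and is not separate evidence, did not pass (median 0.003, camera adjusted p = 0.806). It passed at -0.32 only over probes brighter than the median probe. The granulocyte mean minus the haemoglobin mean differed between the groups by -0.431, near the larger within-group SD of 0.404. It was -2.05 and -2.62 on transgenic replicates 1 and 2, and -1.99 and -1.82 on knockin replicates 1 and 2. Fewer granulocytes in transgenic or more in knockin thymus stays open as a biological difference between the genotypes, untested.

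For the neighbouring genes, 7 called genes had another called gene within 10 places, the 5 from Gbp11 to Zfp326 and the pair S100a8 and S100a9, and none of 10000 random draws had more than 6 (permutation p = 1e-04, the smallest these draws can give). That p is for all 7 genes and not for the block, whose 5 genes alone lie below the highest random count of 6. As the window was chosen after the run of genes was seen, the p bears on chance placing alone. The count was 5 against at most 2 in 1000 draws within 2 places, but 9 against at most 9 within 50 places. A sequence variant under a single probe does not account for Zfp326, where 3 of 3 probes passed, but for the rest of the block it cannot be told apart from a change in expression, as 0 other block genes had a second probe above background. One copy-number change over the whole block would move its genes together, whereas 1 gene, Lrrc8c, passed in the opposite direction. As Lrrc8c was read by 1 probe, which may itself lie over a variant, this cannot decide on a copy-number change. The block lies on chromosome 5. A candidate explanation for it is a segment that differs between the lines, either strain-derived sequence carried along or the surroundings of an insertion site. Nanos3, beside Mir181d, was not among the genes measured within 20 places of the block. Its difference might, separately, be a local effect of the knockin allele. Neither explanation was tested.

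For the histone genes (median 0.59 over all 54), a larger share of cells in S phase would raise replication genes too. The 23 genes of the replication and mitosis list above background had a median of -0.055 and an upper quartile of -0.003. As that list mixes replication with mitosis genes, its median does not measure S phase alone. Transgenic replicate 2 was not the only source of the pattern, as the median without it was still 0.4. The size of the pattern leaned on that array, since the median was 0.811 without transgenic replicate 1. With the 3 female arrays the median was 0.673, so the pattern did not rest on the sex of knockin replicate 2. Because replication-dependent histone transcripts lack a poly(A) tail, their signal may also vary with RNA quality or with priming during amplification, which was not tested. The H2A values were small, but the brightest H2A probes may be compressed, so this explanation stays open beside a difference between the genotypes.

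The 4 arrays can be divided into 2 and 2 in 3 ways, too few for a share under 0.05. Only 1 of these splits, the real one, reached 36 probes, and the highest other count was 4, from the split by place on the slide. At an unadjusted p under 0.05 that split had 4044 probes against 2097 for the real one, which points to a structure of the samples other than genotype. That split also follows array signal. Transgenic replicate 1 and knockin replicate 2 had 20167 and 20085 probes above background, and transgenic replicate 2 and knockin replicate 1 had 19518 and 19272. Place on the slide and array signal cannot be told apart here.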
